A study of Homo sapiens with 9 samples.

How the data were processed

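Gene expression was measured in total RNA of ZR-75-1 cells on 9 Affymetrix Human Gene 2.0 ST arrays, 1 colour and 1 sample per array. Per the labels' protocols, the cells received a lipid transfection reagent with 50 nM miR-150-5p mimic, with 50 nM negative control RNA, or with no RNA (mock), and RNA was taken at 48 h and labelled with biotin by a FlashTag kit. Each of the 3 groups has 3 arrays. The design text gives triplicate transfections and does not say whether these were independent experiments, so the p-values measure the spread between these samples, part of which may be technical.

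The deposited table gives 1 log2 value per probeset and array for 53617 probesets, with no missing values and a range from 1.16 to 13.7. Per the submitters' processing notes the authors used RMA, which corrects background, equalises the arrays and summarises probes on the log2 scale; its version, the probe annotation and the genome build are not given in the sources used here. No coordinates are printed for that reason. The array medians over all probesets lay between 4.22 and 4.27. The table holds no detection call or background value, so the number of arrays limits the precision, and a low value cannot be separated from background probeset by probeset.

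Probesets were named through a table of the platform's annotation, which pairs 16098 of them with 1 gene symbol, none with several, and leaves 37519 unnamed here. All 16098 gene identifiers matched the RefSeq gene table of GRCh38.p14, which was used for names only and changed 0 symbols. For the 779 genes with several probesets the one with the highest mean over the 9 arrays was used, which left out 1214 probesets. This gave 14884 genes, 11915 of them protein-coding and 1072 microRNA genes. No filter on dim genes was applied in the main analysis.

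The deposited log2 values were fitted without further normalization in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), 1 mean per group over all 9 arrays, so that the 3 groups share 1 estimate of the spread with 6 residual degrees of freedom. The 3 comparisons were mimic against negative control, mimic against mock, and negative control against mock. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, with a threshold of 0.05. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so no gene was tested that way. In 822 genes the table holds 1 identical value on all 3 arrays of a group, VEGFA in the negative control among them, so the spread there is estimated as 0 in that group; 1 of these was called against the negative control and 0 against mock. Errors of log2 changes are limma's moderated standard errors.

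The gene lists, the rule for naming genes, the tests of the comparisons and the alternatives were fixed before the data were examined. 21 lists were fixed: reported miR-150-5p targets, estrogen-induced genes, luminal identity, basal and myoepithelial markers, epithelial adhesion, mesenchymal genes, DNA replication, mitosis, type I interferon response, NF-kB response, p53 targets, apoptosis regulators, cholesterol synthesis, unfolded protein response, hypoxia and glycolysis, microRNA machinery, ribosomal proteins, fibroblast, leukocyte and endothelial markers, and mitochondrially encoded genes. List members whose probeset has no name in the table count as not measured, which left 13 of 19 reported targets, 6 of 18 basal and myoepithelial markers and 4 of 13 fibroblast markers, for example. The mitochondrially encoded genes had no measured member, so 20 lists were tested with camera (preset correlation 0.01), which compares a list's genes with all other genes, adjusted over the 20 lists of a comparison. The genes named are the 12 largest rises and 12 largest falls of mimic against negative control, and the 6 and 6 of the other comparisons. They had to pass the threshold, to show no overlap between the arrays of the 2 groups, to have a mean in the higher group above the median of all genes tested (5.44), and to carry no name of a small RNA, an antisense transcript or an uncharacterised locus. Where fewer than 5 genes passed, the 5 with the lowest p are named as not passing. From each list up to 4 passing members with the largest change are named, or the member with the lowest p, and each measured member of the list of reported targets was examined. Genes named outside this rule are marked as such.

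Because both comparisons of the mimic use the same 3 mimic arrays, 100 simulations of 9 unchanged arrays were run. They used limma's moderated spread of each gene and drew genes independently. They gave the overlap and correlation that arise with no effect under these settings. The analysis was tested on simulated data for the real 14884 genes, with 200 genes changed in each of 10 runs. The changed genes were all drawn from those above the median mean intensity. Noise was drawn independently at limma's moderated spread of each gene, with the same quality on all arrays. The shares recovered therefore do not cover dim genes, correlated genes or arrays that stand apart. For mimic against negative control it recovered 72.4% of the genes changed by 0.5 on the log2 scale, 99.9% at 1 and 100% at 1.5, with 7.6 false calls per run on average. For mimic against mock the shares were 73.6%, 99.7% and 100%, with 10.4 false calls. For negative control against mock, simulated without change, there were 0 calls.

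The alternatives were a fit on 6 arrays only, the replicate number as a block, 2 filters on dim genes, every probeset, the mean of a gene's probesets, a mean-variance trend with robust estimation, array weights, quantile normalization, median centring, other thresholds, other tests of gene lists, and leaving out each array in turn. A test of genes with a miR-150-5p seed match in the 3' untranslated region was planned and was not run, since transcript sequences were not used here.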

Results

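Transcript levels were compared in ZR-75-1 cells, an established line of estrogen receptor-positive breast cancer cells, 48 h after transfection. The 9 arrays formed 3 groups of 3: cells given the lipid reagent alone (mock), cells given 50 nM of a negative control RNA, and cells given 50 nM of a mimic of miR-150-5p, a microRNA best known from lymphocytes. The stated purpose was to restore this microRNA to an estrogen receptor-positive line. Median log2 intensity over all probesets was between 4.22 and 4.27 on every array, and the correlation of an array with the others of its group averaged between 0.993 and 0.995. The first principal component, with 24.0% of the variance, placed the 3 mimic arrays at scores from 6.62 to 15.6 and the 6 control arrays from -9.74 to -0.41. Mimic replicates 1 and 3 lay far apart on the second component (11.7 and -16.9, 19.3% of the variance). Mock replicate 3 (-9.74 and -5.20) lay beside negative control replicate 3 (-9.18 and -4.79) and away from mock replicates 1 and 2 (-1.39 and 6.71, -0.41 and 10.4). It correlated with its own group (mean 0.9935) no better than with all other arrays (0.9936), as did mimic replicate 2 (0.9940 and 0.9941).

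The probeset of the microRNA gene itself, MIR150, did not separate the groups. Its log2 intensity was 4.06 ± 0.37 (SD, n = 3) in mock, 4.09 ± 0.14 in negative control and 4.20 ± 0.26 in mimic arrays, with a log2 change of 0.11 ± 0.19 (SE) against the negative control and an adjusted p = 0.851. Whether this probeset detects the transfected mature strand is not given in the sources used here, so it does not check delivery of the mimic.

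The comparison of mimic with negative control RNA, at the same dose, asked which transcripts differ when the transfected RNA is miR-150-5p. ADAM19, a membrane metalloprotease, had the largest fall: its log2 intensity fell by 1.54 ± 0.10 (SE, n = 3 arrays per group), which is 2.92-fold, from 7.08 ± 0.18 (SD) to 5.54 ± 0.08, with an adjusted p = 0.000869. SLC25A15, the mitochondrial ornithine carrier, changed by -1.14 ± 0.14 (SE) and PSAT1, an enzyme of serine synthesis, by -0.84 ± 0.10. SESN3, a stress-response sestrin, had the largest rise among the genes named, 0.95 ± 0.10 or 1.93-fold, with an adjusted p = 0.0106. PGR, the progesterone receptor and a classical estrogen-induced gene, rose by 0.58 ± 0.08, and ESR1, the estrogen receptor alpha gene, by 0.46 ± 0.07.

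**Figure D1:**
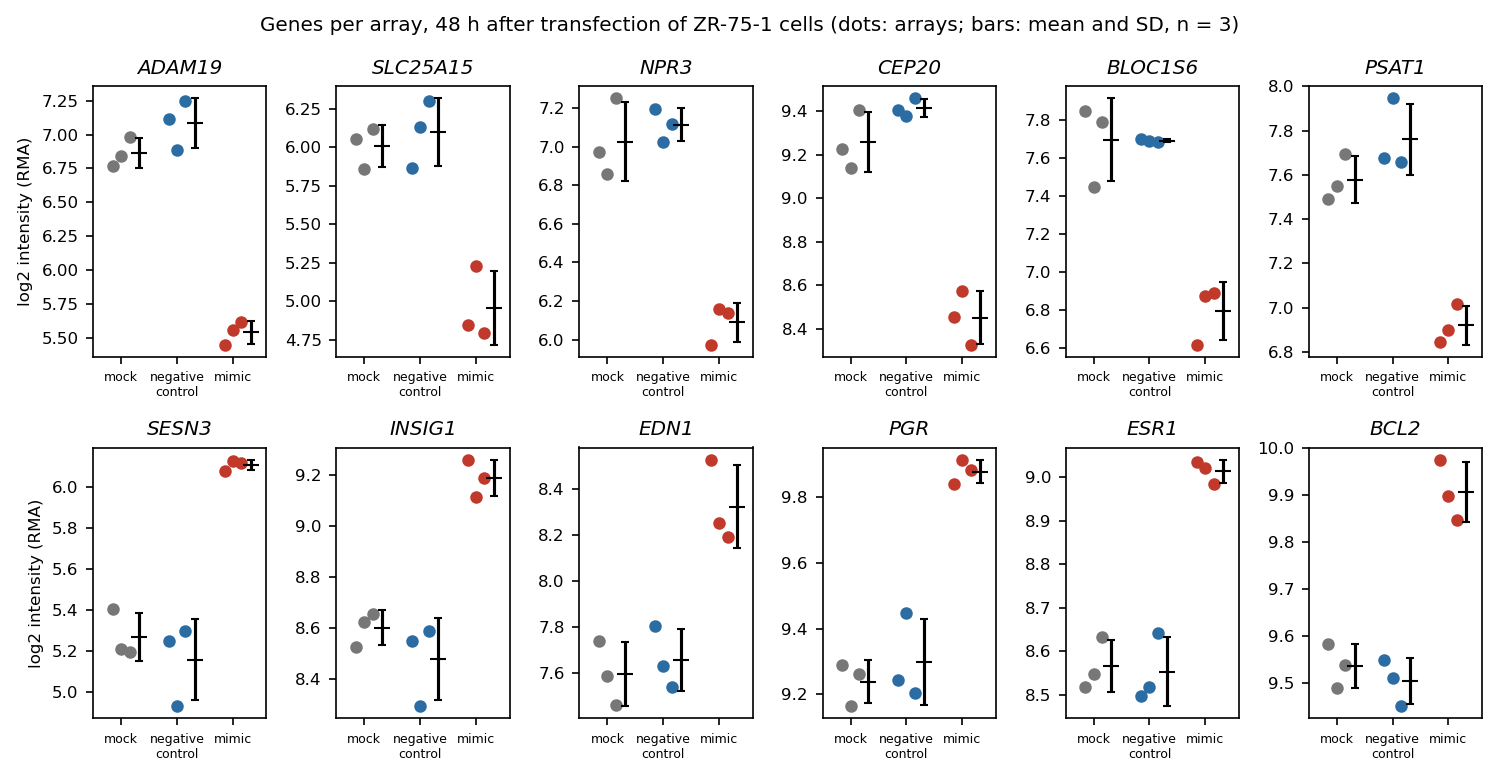
Log2 intensity (RMA) of 12 genes on each of the 9 arrays, by group (grey mock, blue negative control, red mimic); dots are arrays, and the bars beside them are the mean and SD of n = 3. The vertical axes differ between genes and do not start at 0; in each panel the 3 mimic arrays lie apart from the 6 control arrays, below them for ADAM19 (mimic mean 5.54) and above them for SESN3 (mimic mean 6.11).

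Of 14884 genes tested, 82 passed: 30 rose by 1.30-fold to 2.29-fold and 52 fell by factors of 1.30 to 2.92. All 82 had no overlap between the 3 mimic and the 3 negative control arrays, which the call itself makes likely. Over all genes this held for 16.4%, where chance gives 10%. The other falls named were ZNF25, a zinc finger protein (-1.13 ± 0.16), MT2A, a metal-binding metallothionein (-1.10 ± 0.17), MMD (-1.05 ± 0.09), NPR3, the clearance receptor for natriuretic peptides (-1.02 ± 0.11), CEP20, a centrosomal protein (-0.96 ± 0.09), SLC49A4 (-0.94 ± 0.09), BLOC1S6, a subunit of a complex for lysosome-related organelles (-0.90 ± 0.11), VPS25, a subunit of the ESCRT-II sorting complex (-0.78 ± 0.13), and LIMCH1, an actin-associated protein (-0.76 ± 0.07). The other rises were GDF15, a stress-induced cytokine (0.80 ± 0.13), OPN3, an opsin (0.73 ± 0.12), INSIG1, a sterol-regulated protein that holds back cholesterol synthesis (0.71 ± 0.09), GSTM1, a glutathione transferase (0.71 ± 0.12), KL, which encodes klotho (0.67 ± 0.09), EDN1, the precursor of endothelin-1 (0.66 ± 0.11), INSL4, an insulin-like peptide (0.63 ± 0.11), IGFBP6, a binding protein of insulin-like growth factors (0.58 ± 0.09), STX12, a syntaxin of endosomes (0.57 ± 0.09), and RALGPS2, an exchange factor for Ral GTPases (0.54 ± 0.07).

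Among the lists, the hormone-related ones stood higher in the mimic arrays. Of 32 measured estrogen-induced genes, 1 rose (PGR), 1 fell (CA12, a carbonic anhydrase, -0.52 ± 0.09) and 30 did not pass. Adjusted over the list alone, 12 were higher and 3 lower. The list's median log2 change was 0.16, with a camera adjusted p = 0.00295 and an adjusted p = 0.247 with an estimated correlation. Of 16 luminal identity genes, ESR1 and BCL2, an apoptosis inhibitor (0.40 ± 0.07), rose, 0 fell and 14 did not pass, with 5 higher and 0 lower adjusted over the list alone. The median was 0.13, with a camera adjusted p = 0.00331 and an adjusted p = 0.247 with an estimated correlation.

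Lists of proliferation and interferon genes stood lower, without a member that passed. Of 27 DNA replication genes, 24 had a negative log2 change and 0 passed. Adjusted over the list alone, 0 were higher and 4 lower, among them GINS1 (-0.41 ± 0.09). The list's median was -0.10, with a camera adjusted p = 0.000162 and an adjusted p = 0.247 with an estimated correlation. Of 27 mitosis genes 0 passed and 1, CDC25C (-0.44 ± 0.09), was lower adjusted over the list alone, with a median of -0.07, a camera adjusted p = 0.0431 and an adjusted p = 0.680 with an estimated correlation. The mean of the mitosis genes lay 0.17 below the mean of the 6 control arrays in mimic replicate 1, 0.00 below it in mimic replicate 2 and 0.04 above it in mimic replicate 3. Of 27 type I interferon response genes 0 passed and 1, USP18 (-0.74 ± 0.16), was lower adjusted over the list alone. Their median was -0.05, with a camera adjusted p = 0.0431 and an adjusted p = 0.382 with an estimated correlation. The mean of the interferon genes lay 0.10 and 0.15 below that of the control arrays in mimic replicates 1 and 2 and 0.01 below it in mimic replicate 3.

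Some of these list calls against the negative control were lost when 1 array was left out. The estrogen-induced list did not pass without mimic replicate 1 (adjusted p = 0.0650). The mitosis list did not pass without mimic replicate 1 (0.588), negative control replicate 2 or 3 (0.152 and 0.0982) or mock replicate 2 (0.0512). The interferon list did not pass without mimic replicate 1 or 2 (0.0650 and 0.231), negative control replicate 1, 2 or 3 (0.0718, 0.0879 and 0.0757) or mock replicate 2 (0.0520). Luminal identity and DNA replication passed in all 9 of these fits.

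None of the other 15 lists passed. Among the reported miR-150-5p targets, 13 measured of 19 listed, 0 rose, 0 fell, and 0 passed adjusted over the list alone. Their median log2 change was -0.03. MYB, the best known target, changed by -0.13 ± 0.17 with a 95% interval from -0.51 to 0.25, ZEB1 by -0.16 ± 0.10 at a low mean log2 intensity of 2.87, CXCR4 by -0.13 ± 0.24, NOTCH3 by -0.08 ± 0.08 and VEGFA by -0.03 ± 0.08. In all 10 had a negative change, with HMGA2 (-0.0001) and FLT3 (-0.02) close to 0. CCR6 (0.13 ± 0.12), AKT2 (0.12 ± 0.08) and SP1 (0.08 ± 0.07) had a positive one. The sign of MYB, CXCR4, VEGFA, FOXP1, FLT3 and HMGA2 changed in 1 or more alternatives. Of 18 cholesterol synthesis genes INSIG1 rose and PMVK, phosphomevalonate kinase (-0.45 ± 0.06), fell, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0627). Of 11 mesenchymal genes CD44, a hyaluronan receptor (-0.41 ± 0.07), fell, also when adjusted over the list alone (camera adjusted p = 0.160). Of 16 p53 targets GDF15 rose, and of 17 apoptosis regulators BCL2 rose, each the only one adjusted over the list alone too (camera adjusted p = 0.189 and 0.896). The median of the apoptosis regulators was negative (-0.03), while their mean and test were positive. Of 11 unfolded protein response genes 0 passed, and 2 were higher, XBP1 among them (0.38 ± 0.08), and 1 lower adjusted over the list alone (camera adjusted p = 0.398). Of 8 genes of the microRNA machinery and of 11 of hypoxia and glycolysis 0 passed, and 1 each was higher adjusted over the list alone, TNRC6A (0.35 ± 0.06) and KDM3A (0.25 ± 0.07), with camera adjusted p = 0.154 and 0.864. No member passed, over all genes or adjusted over the list alone, among 17 epithelial adhesion genes (lowest p GRHL1, -0.48 ± 0.12; camera adjusted p = 0.215), 12 NF-kB response genes (CXCL3, 0.35 ± 0.12; 0.189), 6 basal and myoepithelial markers (OXTR, 0.37 ± 0.15; 0.864; median -0.06, with a mean just above 0) and 17 ribosomal proteins (RPL6, 0.15 ± 0.08; 0.896). The same held for markers of other cell types: 4 of fibroblasts (FBN1, 0.13 ± 0.07), 6 of leukocytes (LYZ, 0.15 ± 0.08) and 6 of endothelium (PECAM1, 0.47 ± 0.17), with camera adjusted p = 0.864, 0.927 and 0.137. All 6 endothelial markers had a positive change (median 0.15), here and against mock (median 0.15). All 6 lay below the median intensity of all genes.

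The number of genes called was sensitive to single arrays, while ADAM19, MMD, CEP20, SLC49A4 and LIMCH1 passed in each of the 18 alternatives that tested them. Without mimic replicate 1, 2 or 3 the count was 7, 14 or 31, without negative control replicate 1, 2 or 3 it was 11, 10 or 10, and without mock replicate 1, 2 or 3 it was 29, 39 or 121. A fit on the 6 arrays of these 2 groups alone gave 8 genes, 1 higher and 7 lower. With the replicate number as a block 16 passed, 5 higher and 11 lower. PGR passed in 11 of 18 alternatives, ESR1 in 8 and BCL2 in 7. MMD and LIMCH1 fell less against mock (-0.60 and -0.50) than against the negative control (-1.05 and -0.76). The negative control stood above mock for both (0.46 and 0.26), and by less for ADAM19 (0.22), CEP20 (0.16) and SLC49A4 (0.14).

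The comparison of mimic with mock used the other control, lipid without RNA. ADAM19 fell by 1.33 ± 0.10 (2.51-fold, n = 3 per group, adjusted p = 0.00351). SLC25A15 (-1.05 ± 0.14), NPR3 (-0.94 ± 0.11), BLOC1S6 (-0.90 ± 0.11), CEP20 (-0.80 ± 0.09) and SLC49A4 (-0.80 ± 0.09) followed. The largest rises named were GREB1L, a relative of the estrogen-induced GREB1 (0.87 ± 0.12, 1.83-fold), SESN3 (0.84 ± 0.10), CCNP, a cyclin (0.81 ± 0.12), EDN1 (0.72 ± 0.11), INSL4 (0.70 ± 0.11) and PGR (0.64 ± 0.08). GREB1L and CCNP did not pass against the negative control. In all, 45 genes passed, of which 25 rose by 1.33-fold to 1.94-fold and 20 fell by factors of 1.35 to 2.51. All 45 had no overlap between the arrays of the 2 groups, which the call itself makes likely. Over all genes this held for 12.7%, where chance gives 10%.

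Against mock, 6 lists passed, 4 of them also passing against the negative control. Of 32 estrogen-induced genes 1 rose (PGR) and 0 fell; adjusted over the list alone 9 were higher and 2 lower. The median was 0.14, the camera adjusted p = 0.000258 and the adjusted p = 0.202 with an estimated correlation. Of 16 luminal identity genes ESR1 rose (0.45 ± 0.07), with 4 higher adjusted over the list alone, a median of 0.11, a camera adjusted p = 0.00617 and an adjusted p = 0.202 with an estimated correlation. Of 18 cholesterol synthesis genes INSIG1 rose (0.59 ± 0.09) and 0 fell, with 1 higher and 1 lower adjusted over the list alone, a median of 0.13, a camera adjusted p = 0.0289 and an adjusted p = 0.202 with an estimated correlation. Of 8 genes of the microRNA machinery TNRC6A, a scaffold of the silencing complex, rose (0.44 ± 0.06); 2 were higher adjusted over the list alone and all 8 had a positive log2 change. The camera adjusted p = 0.00312 became an adjusted p = 0.286 with an estimated correlation. Of 27 DNA replication genes 0 passed, and 2 were lower adjusted over the list alone, TYMS (-0.33 ± 0.07) among them. Their median was -0.10, with a camera adjusted p = 0.00312 and an adjusted p = 0.286 with an estimated correlation. Of 27 type I interferon response genes 0 passed, also adjusted over the list alone. Their median was -0.07, with a camera adjusted p = 0.0255 and an adjusted p = 0.307 with an estimated correlation. Without mock replicate 3 luminal identity (adjusted p = 0.0518), DNA replication (0.0913), the interferon list (0.0518) and cholesterol synthesis (0.0560) did not pass. Cholesterol synthesis also did not pass without mock replicate 1 (0.0558) or mimic replicate 1 (0.189), nor the interferon list without mimic replicate 2 (0.221).

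The 27 mitosis genes did not pass against mock: their median was 0.02, their mean -0.01, and the camera adjusted p = 0.801. Of the 13 reported targets 0 passed, also adjusted over the list alone, and MYB changed by -0.02 ± 0.17. Several genes named against the negative control did not pass against mock: GDF15 (0.48 ± 0.13, adjusted p = 0.197), OPN3 (0.53), GSTM1 (0.71, adjusted p = 0.0540), KL (0.41), IGFBP6 (0.29, adjusted p = 0.305), STX12 (0.39), BCL2 (0.37), ZNF25 (-0.66, adjusted p = 0.169), MT2A (-0.78), VPS25 (-0.70), CA12 (-0.40), CD44 (-0.33) and PMVK (-0.31). All kept their sign. The p53 targets had a median of -0.04 and a mean of 0.02, with a camera adjusted p = 0.806. Only ADAM19 passed in all 18 alternatives here. Without mimic replicate 1, 2 or 3 the count of genes was 1, 1 or 4, without negative control replicate 1, 2 or 3 it was 1, 10 or 1, and without mock replicate 1, 2 or 3 it was 2, 5 or 2, while a fit on the 6 arrays of these 2 groups alone gave 1 gene. With the replicate number as a block 3 genes passed.

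**Figure D2:**
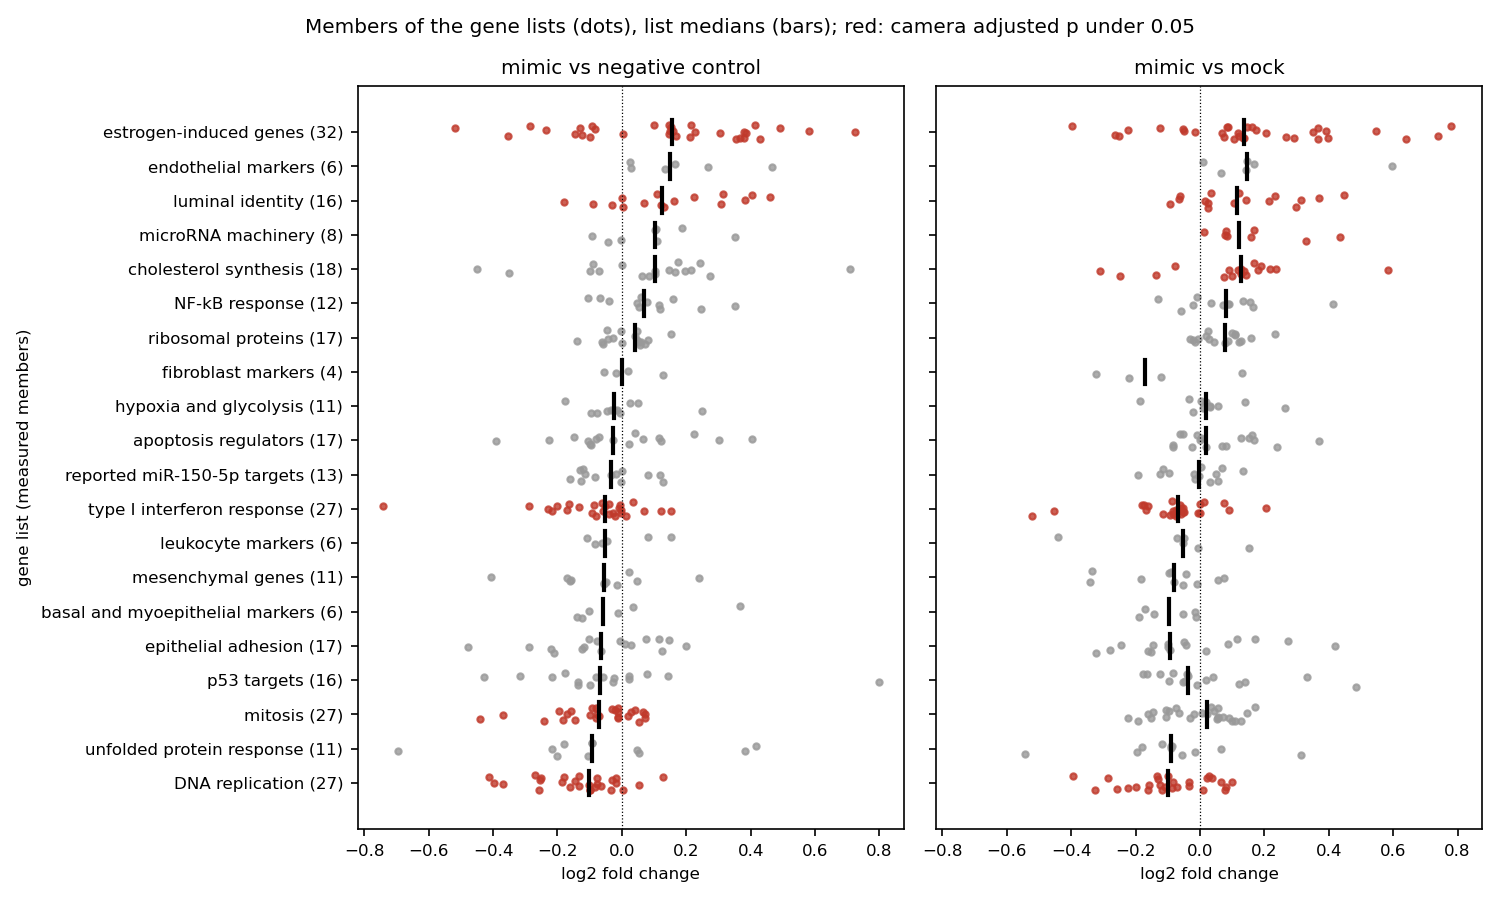
Log2 fold change of each measured member (dots) of the 20 gene lists, mimic against negative control on the left and mimic against mock on the right, with the number of measured members in brackets and list medians as black bars. Lists in red have a camera adjusted p under 0.05 at the preset correlation of 0.01, 5 on the left and 6 on the right; 0 lists pass with an estimated correlation.

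The comparison of negative control RNA with mock gives the background of transfecting an RNA as such. No gene passed in limma's test: the lowest adjusted p was 0.976, and 622 of 14884 genes had an unadjusted p under 0.05, against 1871 for mimic against negative control and 1594 for mimic against mock. The 5 genes with the lowest p, none of which passed, were MMD (0.46 ± 0.09), HOXC13 (0.46 ± 0.09), KRTAP10-1 (-0.98 ± 0.21), SIGLEC7 (-0.49 ± 0.11) and GPHB5 (-0.32 ± 0.07). Non-overlapping arrays were found for 8.10% of genes, where chance gives 10%. ADAM19 differed by 0.22, PGR by 0.06 and ESR1 by -0.01 on the log2 scale. Of the lists 1 passed: of 27 mitosis genes 0 passed singly, also adjusted over the list alone, and 23 had a positive log2 change, BIRC5 with the lowest p (0.21 ± 0.07). Their median was 0.06, the camera adjusted p = 0.0247 and the adjusted p = 0.770 with an estimated correlation. The list did not pass without mock replicate 1 or 2 (adjusted p = 0.204 and 0.415) or negative control replicate 2 or 3 (0.171 and 0.228). The estrogen-induced list (camera adjusted p = 0.660), luminal identity (0.637), DNA replication (0.297) and the interferon list (0.964) did not pass. The microRNA machinery did not pass either (0.138), with 7 of 8 genes positive and a median of 0.08, against 0.12 for mimic against mock.

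Changes in the mimic arrays against both controls were shared by 32 genes, 13 higher and 19 lower, and 0 genes passed in opposite directions. The 19 lower genes included ADAM19, SLC25A15, NPR3, CEP20, SLC49A4, BLOC1S6, MMD, LIMCH1 and PSAT1, and the 13 higher ones SESN3, INSIG1, EDN1, INSL4, RALGPS2, PGR and ESR1. All 82 genes called against the negative control had the same sign against mock, and all 45 called against mock had the same sign against the negative control. Both comparisons use the same mimic arrays, so part of this overlap and of the shared signs may come from them. Simulated unchanged groups gave an overlap of 0.01 genes on average and at most 1, and independent lists of the observed sizes would share 0.0504 higher and 0.0699 lower genes. The simulation drew genes independently, so its values may differ from what correlated genes give with no effect. Across genes, which are not independent replicates, the log2 changes of the 2 comparisons correlated with r = 0.727, against 0.50 in the simulated groups, and had a covariance of 0.0208 against 0.00689, a difference of 0.0140.

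**Figure D3:**
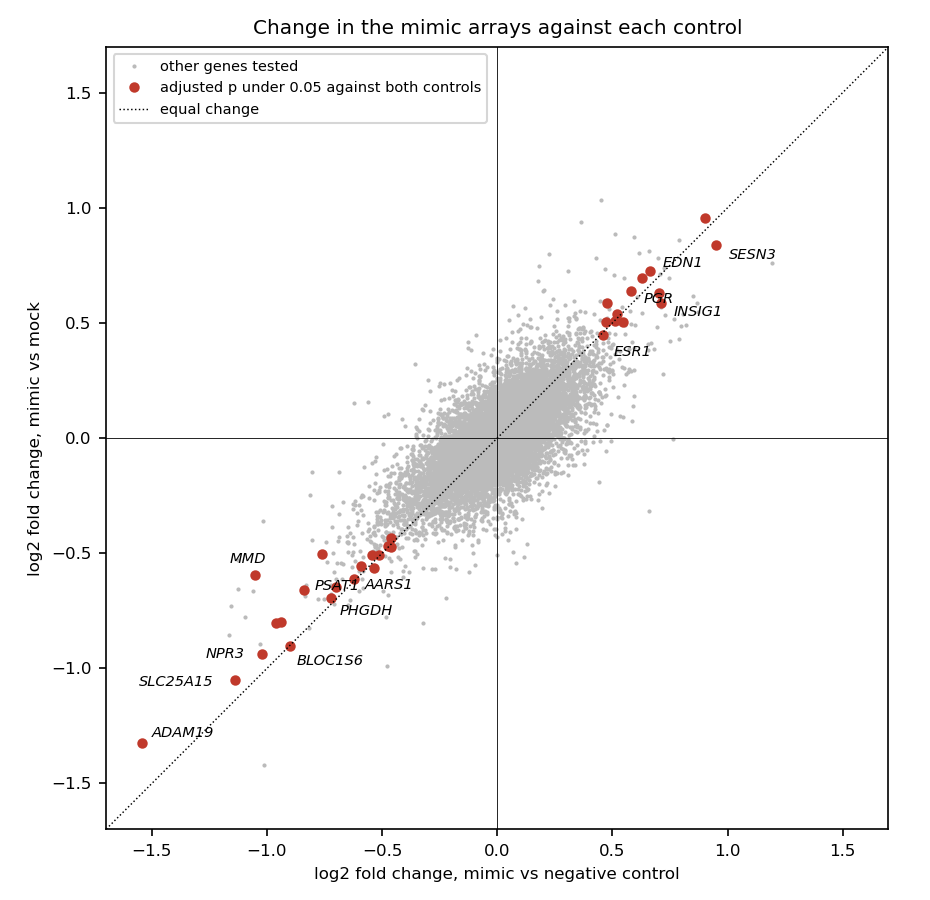
Log2 fold change of each tested gene in the mimic arrays against negative control (horizontal axis) and against mock (vertical axis), with the 32 genes that passed against both controls in red and the line of equal change dotted. ADAM19 lies farthest from 0 among these 32, at -1.54 and -1.33, and SESN3 is among the highest, at 0.95 and 0.84; the 2 axes share the mimic arrays.

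The overlap count of 32 genes was also sensitive to single arrays. Without mimic replicate 1, 2 or 3 it was 1, 1 or 4, without negative control replicate 1, 2 or 3 it was 1, 7 or 1, and without mock replicate 1, 2 or 3 it was 2, 4 or 2. Among the 32 were 2 of the 4 genes without mimic replicate 3, 1 of the 2 without mock replicate 3, and all in the other fits. With the replicate number as a block the count was 3.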

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

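Of the 37519 probesets without a gene name here, tested by themselves, 2 passed for mimic against mock, 1 higher and 1 lower. The rule marked this count because 1 passed for negative control against mock, and so small a margin decides nothing. For mimic against negative control 1 passed, which was lower. No identity can be given here for the probesets that passed. An unadjusted limma p under 0.05 was found for 2724 against the negative control and 2635 against mock, with 1563 for negative control against mock. Groups of 3 arrays are too small for the rule on outlying samples, so it was not applied.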

How the results depend on the processing

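All alternatives were chosen before the data were examined and none was added. The 44 calls of named genes kept their sign in all 790 values. This decides little, as leaving out 1 array cannot reverse groups without overlap. The 93 comparisons not passing changed sign in 68 of 1624. The counts moved. In the order mimic against negative control, mimic against mock and both controls, they were 82, 45 and 32. A fit on only the 6 arrays compared, with fewer degrees of freedom, gave 8 and 1 genes (7 and 1 shared with the main calls). Fewer genes tested gave more calls: 170, 56 and 49 for genes at or above the 25th percentile of mean intensity, and 263, 102 and 89 at or above the median. Testing every probeset, named or not, gave 6, 3 and 2. A mean-variance trend with robust estimation gave 169, 66 and 59, and array weights 268, 57 and 46; the cause was not tested. An adjusted p under 0.10 gave 230, 82 and 65, and a minimum fold change of 1.5 gave 38, 23 and 17. The mean of a gene's probesets (79, 43 and 31), quantile normalization (109, 39 and 33) and median centring (112, 48 and 36) stayed within 1.5 times in total; median centring moved 30 higher and 52 lower against the negative control to 50 and 62. Quantile normalization turned the split against mock from 25 higher and 20 lower to 17 and 22. Negative control against mock gave 0 genes under each alternative.

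Same-numbered arrays were only weakly alike in their deviations from their group means. The correlations were 0.11, 0.03 and 0.06 for mimic and negative control, and 0.05, -0.06 and 0.10 for mimic and mock. For negative control and mock they were 0.06, 0.00073 and 0.13. Each mimic array correlated best with the negative control array of its own number; with mock arrays this held in replicate 3 only, for mimic and for negative control. Whether the numbers pair the arrays thus stays open. With the replicate block 16, 3 and 3 genes passed, all among the main calls, and the list counts stayed at 5, 6 and 1.

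Leaving out 1 array at a time gave 7 to 121 genes for mimic against negative control, 1 to 10 for mimic against mock and 1 to 7 for both. These fits have fewer arrays.

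The counts of gene lists were 5, 6 and 1 for mimic against negative control, mimic against mock and negative control against mock. With an estimated correlation they were 0, 0 and 0, with fry 3 (3 higher and 0 lower, against 2 and 3), 5 and 0, with genes at or above the median 4, 5 and 0, and with quantile normalization 5, 4 and 0; the cause was not tested. Under fry DNA replication (adjusted p = 0.0501), mitosis (0.547) and the interferon list (0.168) did not pass against the negative control and cholesterol synthesis did (0.0291); against mock DNA replication (0.167) and the interferon list (0.184) did not pass and mesenchymal genes did (0.0326). The counts ranged from 2 to 6, 2 to 7 and 0 to 2 with 1 array left out. Against the negative control 2 lists passed without mimic replicate 1, and 3 without mock replicate 2 or negative control replicate 2 or 3. Against mock 2 passed without mock replicate 3. For negative control against mock 2 passed without mock replicate 3 or negative control replicate 1, and 0 without mock replicate 1 or 2 or negative control replicate 2 or 3. No list call changed direction in an alternative.

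The MIR150 value against mock was -0.0866 with array weights and -0.0674 (without mock replicate 3) to 0.30 with 1 array left out; against the negative control it was -0.03 to 0.23, and for negative control against mock -0.18 to 0.19. No seed-match test was run, with any of its alternatives. The table gives no background, and where intensity is below the median of all genes small changes cannot be measured well: 19 of 27 interferon, 9 of 11 mesenchymal, 9 of 12 NF-kB, 5 of 6 leukocyte, 4 of 6 basal, 4 of 13 reported target and all fibroblast and endothelial genes.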

Other observations

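The following 4 genes, the enzymes of serine synthesis and AARS1, were chosen after their values were seen. The 3 enzymes of serine synthesis fell against the negative control: PHGDH by 0.72 ± 0.09 on the log2 scale (SE, n = 3 per group, adjusted p = 0.0153), PSAT1 by 0.84 ± 0.10 and PSPH by 0.42 ± 0.07 (adjusted p = 0.0401). AARS1, the cytosolic alanyl-tRNA synthetase, fell by 0.62 ± 0.07 (adjusted p = 0.0107). Against mock PHGDH (-0.70), PSAT1 (-0.66) and AARS1 (-0.61) passed, and PSPH did not (-0.39 ± 0.07, adjusted p = 0.0721). Of 12 other genes of the amino acid response and 16 other cytosolic tRNA synthetases, 0 passed in limma against either control.

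Among 1072 microRNA genes, also outside the naming rule, 4 rose and 1 fell against the negative control, and 4 rose against mock. This is about as often as over all 14884 genes, where 82 and 45 passed, so microRNA genes do not stand out as a class. MIR23B rose against both controls (0.47 ± 0.07 and 0.58 ± 0.07), and its cluster neighbour MIR27B passed against mock (0.73 ± 0.09) and had 0.47 ± 0.09 against the negative control (adjusted p = 0.0594). AOPEP, the gene that hosts this cluster, did not pass (0.36 ± 0.11 and 0.43 ± 0.11). MIR548F2 rose against both (0.90 ± 0.15 and 0.95 ± 0.15) at a low mean log2 intensity of 4.59. DSG2, a desmosomal cadherin (-0.72 ± 0.12), WT1 (-0.48 ± 0.08) and TOX3 (0.48 ± 0.08), single genes picked after their values were seen, also passed against the negative control.

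The patterns below were noticed in these arrays and tested on the same arrays. The tests of an amino acid response, of the other synthetases against AARS1 and of leaving out mimic replicate 1 or 2, and the counts of genes over splits of the 6 arrays were written after the values they measure had been seen, in whole or in part. The other tests were written before.

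The change of 32 genes against both controls was set against a single mimic array that stands apart and against the accident of how arrays fell into groups. Without mimic replicate 3 the median absolute log2 change of the 32 genes was 1.07 times that with all arrays. The genes were chosen for passing with that array included, so this leaves the array open as a part of the cause. Without it 4 genes passed against both controls, 0 higher and 4 lower, and 2 of them were among the 32. Of 100 of the 840 ways to regroup the 9 arrays, 2 gave as many genes, the real one with 32 and one with 35 that keeps the 3 mimic arrays together and mixes the controls. This share is under 0.05, the limit set in advance, which argues against the accident of grouping for this count. Another drawn grouping that kept the mimic arrays together gave 25, and every one that split them gave 0. The regroupings thus show that the 3 mimic arrays differ from the controls as a set, and cannot tell why. An effect of the transfected miR-150-5p strand also stays open, and whether the genes carry its seed match was not analysed here.

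The higher level of the estrogen-induced and luminal lists was set against single mimic arrays and against a trend with intensity. Without mimic replicate 3 the mean log2 change of their 48 members was 1.09 times that with all arrays (0.14), without replicate 2 it was 1.04 times and without replicate 1, where the pooled members stood highest, 0.874 times; without replicate 1 the estrogen-induced list did not pass (adjusted p = 0.0650). The members' median of 0.15 lay at percentile 100 of 10000 random lists matched on mean intensity, above the 0.05 that marked their upper tail. On each mimic array the 48 members stood above the mean of the control arrays, by 0.18, 0.14 and 0.12 in replicates 1, 2 and 3. The lists were picked for passing with all arrays included, so leaving out 1 array decides little about its part. Random lists of like intensity did not rise as much, which argues against such a trend as the whole source. The percentile shows no more than that, since the lists were picked for standing above other genes in these arrays. The random lists also drew unrelated genes, while list members may vary together. A hypothesis left open is higher estrogen receptor activity along with the rise of ESR1, which the design does not test, and the lists' calls are lost with an estimated correlation (adjusted p = 0.247). The estrogen-induced genes did not move as one against the negative control. PGR rose and CA12 fell (-0.52 ± 0.09), and adjusted over the list alone 12 were higher and 3 lower.

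The lower serine synthesis genes and AARS1 had a mean log2 change of -0.65, and 1.05 times that without mimic replicate 3, which decides nothing, since they were chosen as passing falls. A lower amino acid response, driven by the transcription factor ATF4, is a candidate explanation: 12 other genes of this response had a median log2 change of -0.13 against the negative control (camera p = 0.00086, p = 0.0713 with an estimated correlation) and -0.14 against mock (p = 0.0618 with an estimated correlation), 11 of them negative, with CTH (-1.16 ± 0.26) and ASNS (-0.70 ± 0.18) the lowest and 0 past the threshold singly. This stays a hypothesis, since the members differed widely (SD 0.35) and a link to miR-150-5p was not tested. The ATF4 transcript itself changed by 0.05 ± 0.07, which does not measure the activity of its protein. Lower expression of all cytosolic tRNA synthetases also stays open: the 16 others had a median of -0.0816 against the negative control, short of the -0.10 set in advance (camera p = 0.000908, p = 0.194 with an estimated correlation), and of -0.166, past it, against mock (camera p = 0.000171, p = 0.149 with an estimated correlation), while QARS1 was higher (0.16 ± 0.08 and 0.33 ± 0.08). These medians lay 3.55 and 2.39 of the members' SD above AARS1, which decides nothing, since AARS1 was picked for its fall.

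Splits of the 6 arrays of 2 groups number 10, too few for a share under 0.05. For mimic against negative control the real split gave 82 genes and 5 lists and the highest other 0 and 2; for mimic against mock the values were 45 and 6 against 0 and 4. In each of these 4 counts 1 split, the real one, reached the real value. For negative control against mock the real split gave 0 genes, reached by all 10, and 1 list, reached by 3, with at most 2 lists in another.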
